A study of Mus musculus with 4 samples.

How the data were processed

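RNA from 4 mouse mammary tumours carrying the C3-T transgene was sequenced, 2 of genotype Elf5+/+ (WT) and 2 of genotype Elf5+/- (HET). Per the labels' protocols, the tumours were digested enzymatically, and antibodies to CD45 (leukocytes), CD31 (endothelial cells) and TER119 (erythroid cells) were used in a sort that enriched tumour cells before total RNA was extracted for the libraries. Groups were taken from the genotype characteristic for the WT samples and from the title for the HET samples. The titles of both HET libraries carry the number 3211 and end in T1 and T2. The WT titles carry 3210 and 4972, and both end in T1. The HET libraries may therefore be 2 tumours of a single animal. The labels do not say whether the number in the title names an animal, so p-values measure only the spread between these samples. That spread may be smaller than the spread between animals.

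The deposited table holds estimated counts per gene, which the authors obtained with Salmon, a tool that assigns reads to transcripts without a full alignment, on build GRCm38.p5, per the submitters' processing notes. The Salmon version, the transcript annotation and the strandedness of the libraries are not given in the sources used here. Estimated counts of near-identical genes depend on how reads were shared between them, so pseudogenes, retrocopies and members of multigene families are uncertain. Of 51826 gene identifiers, 51633 matched the GENCODE M21 annotation, 47648 of them with the same version, and symbols and coordinates (GRCm38) come from that annotation. No symbol was found for 193 identifiers, and 143 rows share a symbol with another row. The table held 0 rows that name no gene and 0 columns of other samples.

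Estimated counts were rounded to whole numbers. Total counts were 13152252 in WT 1, 15307939 in WT 2, 14582943 in HET 1 and 12695132 in HET 2. At these depths a count of 0 in a library allows up to 3 counts, or 0.228, 0.196, 0.206 and 0.236 CPM (counts scaled to a common library size) in the same order. These floors cover counting error only, since reads without molecular identifiers are not independent molecules. Mitochondrial ribosomal RNA took 9.74%, 7.26%, 7.56% and 9.90% of counts, and protein-coding genes took 69.7%, 73.4%, 71.2% and 72.7%. No pair of libraries agreed within sampling noise: the chi-square statistic per degree of freedom was between 41.8 and 102. This statistic compares libraries with counting noise alone, so it cannot show whether they come from separate tumours or animals. All 4 libraries were kept as separate samples, as labelled.

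HET was compared with WT in edgeR 4.0.16 (R 4.3.3), using the filter of filterByExpr, TMM normalisation and the quasi-likelihood F test, with genotype as the only term. The filter left 21607 genes, 15856 of them protein coding. The common biological coefficient of variation was 0.46, with 2 residual and 4.08 prior degrees of freedom. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. CPM of single genes are scaled by TMM, and sums over marker lists are CPM of total counts unless stated. With 2 libraries against 2, an exact two-sided permutation test of a single gene cannot give a p below 0.33, so only model-based p-values are given.

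A collection of 32 gene lists (pathways, epithelial states, sample quality and other cell types) was tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the 32 lists. The estimated correlation and fry were alternatives. The lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The rule names Elf5, Fbxw7, Ifngr1, Ifngr2, Cd274 and Snai2 always, with a further gene that is not reported here, then up to 10 passing genes per direction by fold change, then up to 4 passing members of each list. Where none pass, it names the 5 genes of smallest p per direction and 2 members per list, given as values. The 5 genes per direction are taken from those with a mean log2 CPM of at least 1 and groups that do not overlap. Their separation is thus a condition of the choice. Unnamed gene models, pseudogenes and symbols starting with Mir, Snor or n-R5s are skipped, as are immunoglobulin and T cell receptor V, D and J segments.

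Each result was recomputed with relative log expression and upper-quartile scaling, and with library sizes that leave out other cell types, mitochondrial, haemoglobin and immunoglobulin genes. It was also recomputed with no filter beyond 1 count, with a filter of 1 CPM in 2 libraries, and without each library in turn, where the lone library is assumed to vary like the other genotype. DESeq2 1.42.0, limma-voom and robust edgeR were further alternatives for genes, as were an adjusted p under 0.1 and a minimum absolute log2 fold change of 1. Lists were also tested without members of other cell type lists. Tests on protein-coding genes alone and camera on the edgeR count object were added after the data were seen.

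The gene test was tested on simulated data for the 21607 genes of the comparison of HET with WT, with dispersions estimated from the 4 libraries. It recovered 0% of genes seeded at 2-fold, 24% at 4-fold, 70% at 8-fold and 84% at 16-fold, and called 11 of 21377 unchanged genes. The seeded genes, 50 per fold, were drawn from better expressed genes outside the lists, so the rates do not cover genes of low count. A list of 30 genes seeded at 1.74-fold had a camera adjusted p of 7.23e-06 at the preset correlation and 0.97 with an estimated correlation. At the preset correlation 0 of 31 unchanged lists were called. The simulated genes varied independently, so this count cannot show how often lists whose members vary together are called without a change. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.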

Results

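Transcriptomes of C3-T+ mammary tumours with 2 intact copies of Elf5 were compared with those of tumours with a single intact copy. Elf5 encodes an ETS transcription factor of the luminal progenitor and alveolar lineage. Each genotype was represented by 2 libraries, and totals lay between 12695132 and 15307939 counts. The comparison asks which transcripts alter when Elf5 is partly lost in these tumours. The libraries did not divide by genotype: the first principal component, with 62% of the variance, placed the library labelled WT 2 at 137.9 and WT 1, HET 1 and HET 2 at -36.4, -48.5 and -53.0. Across 21607 genes, which are not independent replicates, the Pearson correlation of log2 CPM was 0.905 between both WT libraries, 0.941 between both HET libraries, and 0.934 and 0.943 between WT 1 and HET 1 and HET 2. In the library labelled WT 2, 44.5% of genes had no count, against 29.9% to 31.3% in the other libraries.

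Elf5 (chromosome 2, 103411688 to 103450989, GRCm38, plus strand) was high in WT 1 alone. It stood at 35.6 CPM in WT 1, 4.70 in the library labelled WT 2, 5.39 in HET 1 and 10.6 in HET 2. The log2 fold change of HET over WT was -1.33 ± 0.92 (SE, n = 2 libraries per genotype), and Elf5 did not pass the edgeR quasi-likelihood test (adjusted p = 0.987, unadjusted p = 0.195). Elf5 in the library labelled WT 2 therefore lay below both HET libraries, and without WT 1 the log2 fold change turned to 0.76. A low RNA level does not by itself contradict the label. Other luminal progenitor genes, named after their values were seen, also differed between WT 1 and that library, in both directions. Sox10 stood at 236.7 and 56.4 CPM and Kit at 129.5 and 211.3. Counts over the whole gene cannot show whether the deleted part is missing. Every direction given for HET over WT rests on that label.

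**Figure D1:**
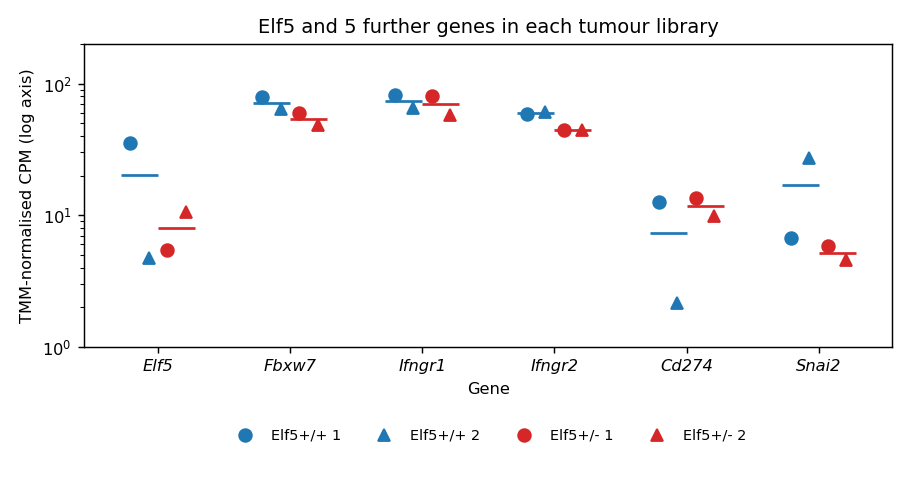
TMM-normalised CPM (log axis) of Elf5, Fbxw7, Ifngr1, Ifngr2, Cd274 and Snai2 in each library. Points are single libraries (blue Elf5+/+, red Elf5+/-, circles library 1, triangles library 2) and bars are means of 2 libraries. Elf5 is at 35.6 CPM in Elf5+/+ 1 and at 4.70 CPM in the library labelled Elf5+/+ 2, below both Elf5+/- libraries.

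No single gene separated HET from WT by the edgeR quasi-likelihood test. Of 21607 genes, 0 passed an adjusted p under 0.05. Among genes that the rule for named genes allows, whose groups do not overlap, those of smallest p higher in HET included Bex1, Bex4 and Rasd1. Bex1 and Bex4 are neighbouring members of an X-linked family of small adaptor proteins, and Rasd1 is a glucocorticoid-induced Ras-like GTPase. Bex1 (chromosome X, 136213972 to 136215513) stood at 1.43 and 0.926 CPM in WT 1 and the library labelled WT 2 and at 19.9 and 11.7 in HET 1 and HET 2 (log2 fold change 3.73 ± 0.56, SE). Bex4 had 0 counts in both WT libraries and 63 and 111 in HET, at least 54.7-fold higher against a floor of 3 counts over the WT group. Rasd1 stood at 10.1 and 6.91 CPM in WT and 35.3 and 34.9 in HET. The immunoglobulin constant gene Ighg1 (log2 fold change 4.29) and the olfactory receptor gene Olfr137 (3.93) completed the higher end, both as uncertain members of multigene families.

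At the lower end of the genes that the rule allows stood Col2a1, Cdk6 and Asns. Col2a1 encodes the collagen of cartilage, Cdk6 a kinase that drives entry into S phase, and Asns asparagine synthetase. Snord33, a small nucleolar RNA gene that the rule skips, had a smaller unadjusted p in edgeR (0.000991) than Col2a1 (0.0014). Col2a1 (chromosome 15, 97975602 to 98004695) stood at 35.8 and 12.8 CPM in WT 1 and the library labelled WT 2 and at 2.01 and 2.45 in HET. Cdk6 (chromosome 5, 3341485 to 3531008) stood at 64.1 and 71.2 CPM in WT and 24.2 and 20.9 in HET (log2 fold change -1.58 ± 0.29, SE). Eno1b, a retrocopy of Eno1 whose counts are uncertain, had a log2 fold change of -1.88. Rnu3a, a small nucleolar RNA gene that shares its symbol with another row, stood at 29.9 and 26.9 CPM in WT and 7.27 and 8.46 in HET.

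At an unadjusted p under 0.05 there were 817 genes, 422 higher and 395 lower in HET, which is 3.78% of those tested. Groups did not overlap for 35.5% of genes, against 33.3% by chance. DESeq2 called 129 genes (47 higher, 82 lower), of which 78 were not protein coding and 13 had 0 counts in one genotype. Among its lower calls 36 were ribosomal RNA gene copies on chromosome 8 whose counts were mostly identical. With identical rows of one biotype counted once the split was 46 higher and 47 lower. The higher calls included Arntl2, Med21, Bhlhe41, Ergic2, Ints13, Tmtc1, Fgfr1op2, Sspn, Rassf8 and Stk38l. They lie close together on distal chromosome 6 and were highest in HET 2, so the split does not count separate changes. Small nucleolar and nuclear RNAs among the calls were mostly lower, such as Snord15a, at 139.6 and 227.7 CPM in WT and 32.3 and 57.1 in HET. The small nuclear RNA rows Gm23444 and Gm23472, with identical counts, were higher. These genes were named after their values were seen, and the cause was not tested. With identical rows counted once, the genes at an unadjusted p under 0.05 in edgeR were 420 higher and 348 lower. Limma-voom called 0 genes, and edgeR with no filter beyond 1 count called 324 (133 higher, 191 lower, or 132 and 149 with identical rows counted once). Without WT 1 edgeR called 657 genes, without the library labelled WT 2 it called 9, and without either HET library it called 0.

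Interferon-stimulated genes were higher in HET as a group. The type I interferon list (antiviral effectors induced through the interferon alpha and beta receptor) rose by camera at the preset correlation (adjusted p = 9.65e-09, median log2 fold change 0.85), with 29 of 30 members above 0. In this list 25 members were higher in both HET libraries than in both WT libraries, against 4241 of all 21607 genes tested. The list had adjusted p = 0.58 with an estimated correlation. Markers of other cell types moved with it, at medians of 1.87 for T and NK cells (1.16 without the library labelled WT 2), 1.10 for pan-leukocyte and 0.80 for macrophage markers (0.17 and -0.17 without that library). Among its members, 0 passed over all genes tested and 3 passed when adjusted over the list alone, all of them 2'-5'-oligoadenylate synthetases that sense double-stranded RNA. Oas2 stood at 10.02 and 5.84 CPM in WT 1 and the library labelled WT 2 and at 64.5 and 26.5 in HET, and Oas1a at 10.7 and 11.1 in WT and 40.1 and 28.2 in HET; Oas3, named after its values were seen, had a log2 fold change of 1.92. Targets of interferon gamma also rose (adjusted p = 1.71e-05, median 0.79, 31 of 35 above 0, 0 passing over all genes and 0 adjusted over the list alone; adjusted p = 0.58 with an estimated correlation). Among them Gbp9, a guanylate-binding protein, stood at 24.5 and 17.7 CPM in WT and 49.9 and 49.6 in HET, and Nlrc5, the transactivator of MHC class I genes, at 21.7 and 21.2 in WT and 56.1 and 32.6 in HET. Without the library labelled WT 2 both interferon lists still passed, at medians of 0.65 and 0.44.

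The list of interferon gamma receptor and JAK-STAT genes did not pass by camera (adjusted p = 0.777, median 0.08). Its members of smallest p, Ptpn6 and Socs3, had log2 fold changes of 0.73 and 0.65. Both were higher in both HET libraries than in both WT libraries. Ifngr1, the ligand-binding chain, stood at 82.0 and 65.4 CPM in WT and 81.1 and 57.7 in HET, and its log2 fold change of -0.09 ± 0.32 (SE) changed sign without WT 1 or HET 2. Ifngr2 stood at 59.2 and 61.3 CPM in WT and 44.3 and 44.2 in HET (log2 fold change -0.44 ± 0.27, SE). Cd274, which encodes PD-L1, stood at 12.5 CPM in WT 1, 2.14 in the library labelled WT 2, 13.6 in HET 1 and 9.80 in HET 2, and its log2 fold change of 0.68 ± 0.80 (SE) turned to -0.10 without the library labelled WT 2. Fbxw7, the substrate receptor of an SCF ubiquitin ligase, stood at 78.8 and 63.8 CPM in WT and 59.3 and 48.3 in HET (log2 fold change -0.41 ± 0.30, SE), and the list of SCF-FBXW7 components had an adjusted p of 0.174. MHC class I genes (adjusted p = 0.287) and myeloid-attracting chemokines (adjusted p = 0.52) did not pass either. Csf1 and Cxcl5, the chemokine list's members of smallest p, had log2 fold changes of -0.81 and -1.20.

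MHC class II genes rose (adjusted p = 0.00178, median 0.90, 10 of 10 above 0; adjusted p = 0.593 with an estimated correlation). Their summed level was 639.9 CPM in WT 1, 18.5 in the library labelled WT 2, 996 in HET 1 and 613 in HET 2. Leukocyte markers moved with them library by library, with pan-leukocyte sums of 343, 24.6, 426 and 369 CPM and macrophage sums of 2522, 171, 4847 and 1988 CPM in the same order. Without the library labelled WT 2 the adjusted p was 0.452 and the median 0.05. H2-Oa, at 0.398 CPM or less in WT and 1.36 and 1.93 in HET, had the smallest p of the list. The list had 0 members passing over all genes and 0 adjusted over the list alone.

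**Figure D2:**
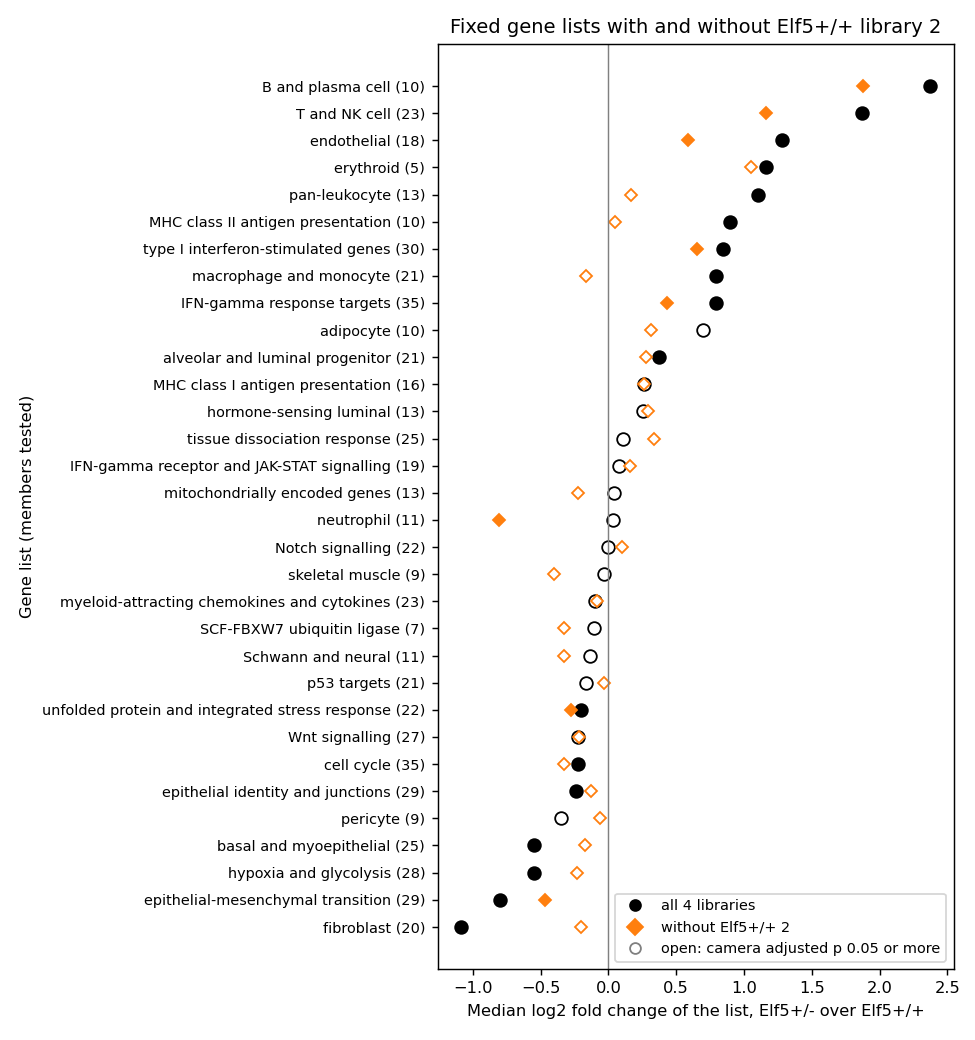
Median log2 fold change (Elf5+/- over Elf5+/+) of each of the 32 gene lists, with the number of members tested in brackets. Black circles use all 4 libraries, orange diamonds leave out the library labelled Elf5+/+ 2, and filled symbols have a camera adjusted p under 0.05 at the preset correlation. Filled symbols number 17 with all libraries and 8 without that library.

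Mesenchymal and basal genes were lower in HET. The epithelial-mesenchymal transition list fell (adjusted p = 1.25e-09, median -0.80, 26 of 29 below 0; adjusted p = 0.58 with an estimated correlation), with 0 members passing over all genes and 0 adjusted over the list alone. Loxl2, a collagen cross-linking enzyme, stood at 179.6 and 243.8 CPM in WT 1 and the library labelled WT 2 and at 82.7 and 78.7 in HET, and Tgfb2 at 37.2 and 35.0 in WT and 16.5 and 11.7 in HET. Snai2, a repressor of epithelial genes, stood at 6.68 CPM in WT 1, 27.1 in the library labelled WT 2, and 5.84 and 4.53 in HET (log2 fold change -1.70 ± 0.71, SE), so its difference lay mainly in 1 library. The list still passed without the library labelled WT 2 (median -0.47). Summed fibroblast markers moved with it, at 26310 CPM in that library against 6196 to 9066 in the others.

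Basal and myoepithelial genes fell (adjusted p = 0.000634, median -0.55, 19 of 25 below 0), and genes of epithelial identity and junctions fell by less (adjusted p = 0.0168, median -0.24, 24 of 29 below 0). Both had adjusted p = 0.58 with an estimated correlation, and neither passed without the library labelled WT 2 (medians -0.17 and -0.13, adjusted p = 0.0872 and 0.452). The call on epithelial identity and junctions also ended without HET 2 (median -0.14, adjusted p = 0.135). Vcan, which encodes the matrix proteoglycan versican, stood at 293.6 and 279.6 CPM in WT and 66.2 and 106 in HET, and Itgb4, the hemidesmosomal integrin beta 4, at 186 and 179 in WT and 91.5 and 91.0 in HET. Epcam stood at 1040 and 1288 CPM in WT and 769 and 613 in HET, and Cd24a had a log2 fold change of -0.91. Alveolar and luminal progenitor genes rose (adjusted p = 0.0477, median 0.37, 13 of 21 above 0; adjusted p = 0.593 with an estimated correlation), but not without the library labelled WT 2 (median 0.28, adjusted p = 0.492). Under upper-quartile scaling the median was as large (0.47) and only the p crossed the threshold (adjusted p = 0.0559). The call also ended with no filter beyond 1 count (median 0.49, adjusted p = 0.111) and without members of the other cell type lists (median 0.35, adjusted p = 0.0527). The size of the median depended on single libraries, at 0.15 without HET 1 and 0.84 without WT 1. The milk protein gene Csn3 stood at 13.3, 3.35, 48.4 and 519.7 CPM in WT 1, the library labelled WT 2, HET 1 and HET 2, so the size of its difference depends on HET 2, while HET 1 was also above both WT libraries. Glycam1 stood at 20.8 CPM in HET 2, 1.17 in HET 1 (18 counts) and 0.0796 CPM or less in WT (1 and 0 counts). The hormone-sensing luminal list did not pass (adjusted p = 0.599). Each of these 4 epithelial lists had 0 members passing over all genes and 0 adjusted over the list alone.

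Most members of the metabolic and stress lists were lower in HET. Hypoxia and glycolysis genes fell (adjusted p = 4e-06, median -0.55, 26 of 28 below 0; adjusted p = 0.58 with an estimated correlation), although not without the library labelled WT 2 (median -0.23, adjusted p = 0.216). Bnip3, a mitophagy receptor induced by hypoxia, stood at 32.4 and 35.1 CPM in WT 1 and the library labelled WT 2 and at 12.3 and 11.4 in HET, and hexokinase Hk2 at 67.1 and 65.2 in WT and 38.3 and 27.8 in HET. The unfolded protein and integrated stress response list fell (adjusted p = 0.0061, median -0.20, 17 of 22 below 0; adjusted p = 0.58 with an estimated correlation), and still did without the library labelled WT 2 (adjusted p = 0.0382). Its member Asns, at 39.9 and 33.0 CPM in WT and 11.8 and 9.72 in HET, was the 1 gene that passed when adjusted over the list alone, against 0 over all genes. Atf4, the transcription factor upstream of Asns, had a log2 fold change of -0.74. The sum over the stress list did not fall, at 3171 CPM in WT 1, 3374 in the library labelled WT 2, 3309 in HET 1 and 3610 in HET 2. With TMM scaling this sum still overlapped between genotypes. Cell cycle genes fell by a small amount (adjusted p = 0.00174, median -0.23, 30 of 35 below 0; adjusted p = 0.593 with an estimated correlation), with Ccnb1 at -0.76. Their sum overlapped between genotypes, at 5185 CPM in WT 1, 4764 in the library labelled WT 2, 4642 in HET 1 and 5305 in HET 2. With TMM scaling it was lower in HET, at 5400, 5182, 4369 and 4973 in the same order. Without HET 1 the median shrank to -0.08 (adjusted p = 0.201). Without the library labelled WT 2 the median was -0.32, larger than with all libraries, with 29 of 35 below 0, and only the p crossed the threshold (adjusted p = 0.0597).

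Notch (adjusted p = 0.512) and Wnt (adjusted p = 0.377) signalling genes and p53 targets (adjusted p = 0.0557, median -0.16) did not pass. The p53 targets passed in the lower direction with no filter beyond 1 count (median -0.25, adjusted p = 0.0147), without WT 1 (median -0.29, adjusted p = 0.014) and by camera on the edgeR count object (adjusted p = 0.0452). The Notch ligand genes Jag1 and Jag2 had log2 fold changes of -0.89 and -1.18. Among lists of sample quality, tissue dissociation genes (adjusted p = 0.695) and mitochondrially encoded genes (adjusted p = 0.508) did not pass, and the median of the latter was 0.04 although camera put it lower. Mitochondrially encoded genes passed in the lower direction without HET 2 (median -0.27, adjusted p = 0.0397). Median and camera also differed in sign for skeletal muscle (adjusted p = 0.967) and Schwann and neural markers (adjusted p = 0.832).

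Markers of other cell types differed between libraries after the sort. Pan-leukocyte markers rose in HET (adjusted p = 0.000477, median 1.10, 13 of 13 above 0; adjusted p = 0.593 with an estimated correlation), as did macrophage and monocyte markers (adjusted p = 0.000344, median 0.80, 21 of 21 above 0; adjusted p = 0.6 with an estimated correlation). Their sums show that this rests on 1 library: pan-leukocyte markers were at 343 CPM in WT 1, 24.6 in the library labelled WT 2, 426 in HET 1 and 369 in HET 2, and macrophage markers at 2522, 171, 4847 and 1988. Apoe, abundant in macrophages, stood at 1221, 124, 2991 and 964 CPM. Without the library labelled WT 2 neither passed, the pan-leukocyte median was 0.17 and the macrophage median turned to -0.17.

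T and NK cell markers rose more (adjusted p = 2.59e-14, median 1.87, 23 of 23 above 0; adjusted p = 0.58 with an estimated correlation), and 6 members passed when adjusted over the list alone, against 0 over all genes. Their sum was 46.4 CPM in WT 1, 15.2 in the library labelled WT 2, and 113 and 117 in HET. Cd3d, a chain of the T cell receptor complex, stood at 2.71 and 2.56 CPM in WT and 11.2 and 12.5 in HET, and Cd3g at 0.955 and 0.214 in WT and 8.83 and 7.42 in HET. B and plasma cell markers rose as well (adjusted p = 0.00163, median 2.37, 8 of 10 above 0; adjusted p = 0.58 with an estimated correlation), with Pax5 the 1 member passing when adjusted over the list alone and 0 over all genes. Their sum was 46.8 CPM in WT 1, 49.6 in the library labelled WT 2, 61.2 in HET 1 and 147 in HET 2. In the WT libraries most of that sum was Ebf1, named after its values were seen (26.8 and 40.2 CPM, against 18.3 and 25.1 in HET). Of its members, 8 of 10 were higher in both HET libraries than in both WT libraries, against 4241 of all 21607 genes tested. Without HET 2 the list still passed, at a smaller median of 1.02 (adjusted p = 0.017). Endothelial markers rose (adjusted p = 9.81e-05, median 1.28, 16 of 18 above 0; adjusted p = 0.58 with an estimated correlation), with Esam at 6.60 and 2.85 CPM in WT and 14.2 and 12.1 in HET. These 3 lists still passed without the library labelled WT 2, at medians of 1.16, 1.88 and 0.58. The 5 tested erythroid markers rose at a summed level of 20.9 CPM or less (adjusted p = 0.0348, median 1.16; adjusted p = 0.58 with an estimated correlation). With no filter beyond 1 count, 11 members had a median of 0.29 (adjusted p = 0.687), and the call also ended without the library labelled WT 2 (median 1.05, adjusted p = 0.426) and without HET 2 (median 0.89, adjusted p = 0.0632).

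Fibroblast markers fell (adjusted p = 9.65e-09, median -1.09, 20 of 20 below 0; adjusted p = 0.58 with an estimated correlation). Their sum was 26310 CPM in the library labelled WT 2 against 9066 in WT 1, 6196 in HET 1 and 7432 in HET 2, and without the library labelled WT 2 the median was -0.20 (adjusted p = 0.0504). Col5a1 stood at 427 and 1232 CPM in WT and 204 and 233 in HET, and Col6a3 at 402 and 768 in WT and 162 and 243 in HET. Pericyte (adjusted p = 0.0524), adipocyte (adjusted p = 0.0683) and neutrophil (adjusted p = 0.695) markers did not pass. Neutrophil markers passed in opposite directions when a WT library was left out, lower without the library labelled WT 2 (median -0.81, adjusted p = 0.034) and higher without WT 1 (median 2.02, adjusted p = 0.0237). Pericyte markers passed in the lower direction without WT 1 (median -0.58, adjusted p = 0.00657) and without HET 2 (median -0.53, adjusted p = 0.0356), and adipocyte markers in the higher direction among protein-coding genes alone (median 0.70, adjusted p = 0.021).

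**Figure D3:**
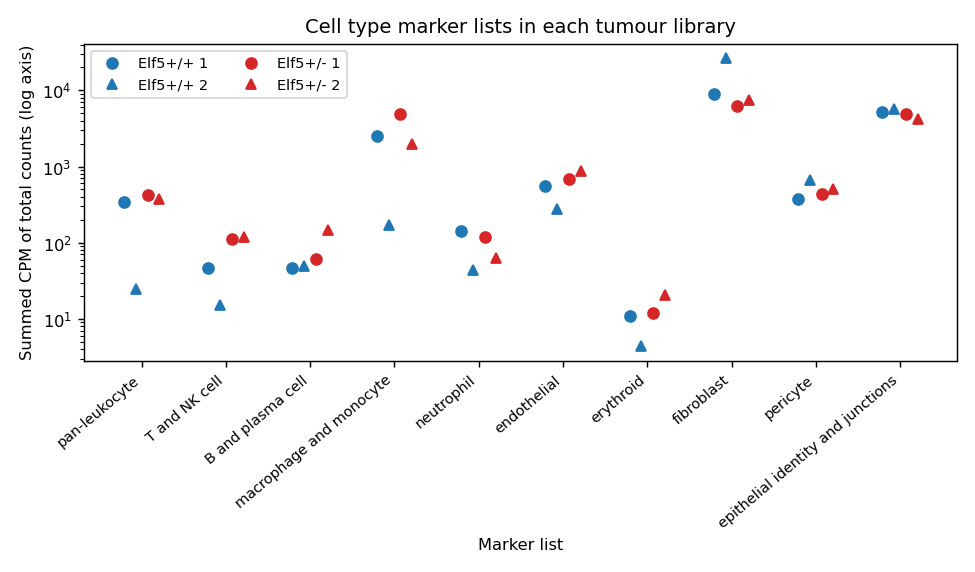
Summed CPM of total counts (log axis) of 10 marker lists in each library. Points are single libraries (blue Elf5+/+, red Elf5+/-, circles library 1, triangles library 2). The library labelled Elf5+/+ 2 has 24.6 CPM of pan-leukocyte markers against 343 to 426 in the other libraries, and 26310 CPM of fibroblast markers against 6196 to 9066.

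Across the 32 lists, camera at the preset correlation called 10 higher and 7 lower in HET, and 0 passed with an estimated correlation (smallest adjusted p = 0.58) or by fry (smallest adjusted p = 0.48). In each list 0 members passed over all genes, and apart from the type I interferon, stress response, T and NK cell and B and plasma cell lists, 0 members passed when adjusted over the list alone. A simulated list with a known change was not detected with an estimated correlation either, although its genes varied independently. In the data the estimated correlation of the called lists ran from -0.019 (basal and myoepithelial) to 0.963 (macrophage and monocyte), and was 0.478 for the type I interferon list. The simulation therefore cannot tell whether low power or members that vary together ended these calls. Nor can the simulation show how often the preset correlation calls unchanged lists whose members vary together.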

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

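The tests on protein-coding genes alone and of camera on the edgeR count object were chosen after the data were seen. The edgeR count of 0 changed genes (817 at an unadjusted p under 0.05) held under both other scalings, library sizes without other cell types, the filter of 1 CPM, robust edgeR (801), limma-voom (920), an adjusted p under 0.1 and protein-coding genes alone (538). With no filter beyond 1 count it was 324 (133 higher, 191 lower), and DESeq2 called 129 (47 higher, 82 lower); the cause was not tested. Leaving out each library in turn gave 0 to 657 changed genes, 0 to 493 higher and 0 to 164 lower. The 657 came without WT 1, when the library labelled WT 2 stood alone, and 9 (1 higher, 8 lower) without the library labelled WT 2. The count of lists, 17, became 0 with an estimated correlation and 0 by fry, and 8 to 20 when a library was left out, with 8 without the library labelled WT 2. Over the 4 omissions the log2 fold change of Elf5 ran from -2.16 to 0.76, of Ifngr1 from -0.40 to 0.086 (0.079 without HET 2), and of Cd274 from -0.10 to 2.45. The median of macrophage markers ran from -0.17 to 4.53, and of neutrophil markers from -0.81 to 2.02. Upper-quartile scaling placed the median of all genes at 0.12, against 0.04 with TMM. In simulation with these dispersions, 0% of 2-fold and 24% of 4-fold changes seeded in better expressed genes were recovered.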

Other observations

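All tests in this part were chosen after the results were seen, and the genes named in it that are not in the rule for named genes were chosen after their values were seen.

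The tumours differed along distal chromosome 6. In 3 of 4 libraries (WT 1, HET 1 and HET 2), the window of 25 neighbouring expressed coding genes with the highest median relative to the other libraries lay there, at log2 medians of 1.18, 0.66 and 2.66. Within it, Mrps35 and Klhl42 were at 440 and 188 CPM in WT 1 and at 348 and 166 CPM in HET 2, while Bhlhe41, Ints13 and Med21 were at 77.6, 40.01 and 15.1 CPM in WT 1 and at 977, 759 and 277 CPM in HET 2.

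The block from Rassf8 to Tmtc1 (chromosome 6, 145746748 to 148444389) holds 17 coding genes above the expression cut of the window scan. Most of them were high together in HET 2, although Mrps35, Klhl42 and Pthlh (90.5 CPM in WT 1 against 41.8 in HET 2) were higher still in WT 1. Far2 lies inside these coordinates but fell below that cut and was not counted (1.43 CPM in WT 1, 3.78 in the library labelled WT 2, 3.70 in HET 1 and 27.8 in HET 2). The median log2 ratio of HET 2 over the library labelled WT 2 was 2.995, with 16 of 17 genes above 1. Among 7560 other blocks of as many genes 0 were as high, the highest at 1.35, and the 6 genes distal of Tmtc1 had a median of -0.51, so a copy number gain in the cells of this tumour is a candidate explanation. The boundaries were drawn after the values were seen, and DNA was not analysed here. The median for HET 2 over HET 1 was 2.25, with 17 of 17 genes above 1, which argues against Elf5 genotype alone for the level in HET 2. HET 1 over the library labelled WT 2 had a median of 0.72, with 5 of 17 genes above 1. The block was chosen for its level in HET 2, so its rank and the ratio to HET 1 are descriptions and not independent tests.

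Transcripts specific to HET 2 were also present at a low level in HET 1. Of 11 coding genes outside distal chromosome 6 with at least 20 CPM in HET 2 and 5-fold less in both WT libraries, 11 exceeded the WT mean in HET 1, at a median of 8.2% of the HET 2 level (interquartile range 6.6% to 14.2%), as cells or RNA shared between the HET tumours could give. The same measure is not specific, because 44 of 45 transcripts specific to the library labelled WT 2 also exceeded the reference in HET 1, at a median of 21.2% (13.8% to 40.9%). Sharing, the common genotype and a possible common animal cannot be told apart with 2 libraries.

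Interferon-stimulated genes were higher in HET while leukocyte markers also varied. Against WT 1 alone, the type I interferon list had a median log2 fold change of 0.65, above those of pan-leukocyte (0.17) and macrophage (-0.17) markers. It lay below those of T and NK cell (1.16) and B and plasma cell (1.88) markers, so this order does not decide on leukocyte RNA. Against the library labelled WT 2 alone, the ratio of the interferon list was 1.14 and those of the pan-leukocyte and macrophage lists 3.45 and 4.18 (log2 of CPM plus 0.5), the order that leukocyte RNA could give. Since each reference is 1 library, more leukocyte RNA remains open despite the CD45 sort; Ptprc, which encodes CD45, stood at 62.1, 2.85, 73.4 and 66.1 CPM in WT 1, the library labelled WT 2, HET 1 and HET 2. More T or NK cells, whose markers had a median of 1.16 against WT 1 alone, may also contribute, and neither the 25 listed markers (23 tested, 0 in another list) nor the genotype label separates this from a response of the tumour cells.

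Rpl10-ps1, a processed pseudogene whose counts are uncertain, had the smallest p of all genes (adjusted p = 0.327 by edgeR), with 0 counts in both WT libraries and 42.2 and 34.7 CPM in HET, at least 341-fold higher against a floor of 3 counts over the WT group. It lies 2.1 Mb from Elf5 on chromosome 2 (105554201 to 105554845), and 46 of 21555 tested genes with a position (0.213%) lie as near. Within 5 Mb of Elf5, 1 of 57 genes had an unadjusted p under 0.05 (1.75%), against 3.79% elsewhere. The median of chromosome 15 was 0.58 log2 units above the other libraries in WT 1, and that of chromosome 16 was 0.63 above in the library labelled WT 2.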
